A study of Mus musculus with 6 samples.

How the data were processed

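RNA from bone marrow of leukemic mice was extracted with TRIzol and made into libraries with a BGI dual-mode mRNA kit, per the labels' protocols. The 6 libraries fall into 2 groups by their titles and genotype labels, 3 labelled Con (Papola floxed and intact) and 3 labelled KO (Papola knockout). The labels name no sort of cells, no batch, no sequencing date and no sex, and call the cell type leukemia. They do not say that the 3 samples of a group came from separate animals. If they did not, the p-values measure only the spread between these samples, which may be technical.

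The deposited table holds estimated counts of reads per gene, not scaled, 1 column per library, per the file headers. Of its 9295 genes, 1449 (15.6%) carry a count that is not whole in some library, so the values are expected counts of the kind that split reads between genes or transcripts, and they were rounded to whole numbers before any test. The aligner and the counting tool are not given in the sources used here. The submitters' processing notes list the build GRCh38, a human assembly, while the gene IDs and symbols are those of mouse, so no coordinates are given. Of the gene IDs, 9257 are found in the mouse RefSeq gene table used here for names, and 9211 of its 21900 protein-coding genes (42.1%) are in the deposited table. Every gene is of the type mRNA, and 4 lists (small nucleolar RNA host genes, mitochondrially encoded genes, nuclear long non-coding RNA and sex-linked check genes) had no gene to test here. A count of 0 in all libraries was found for 54 genes. Since reads of near-identical copies can be split by such counting, values of single copies are uncertain. Every column of the table was matched to a library by its name, and 0 columns were left unused.

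Genes were compared between KO and Con with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with its defaults by group, robust quasi-likelihood fit and test, two-sided), with no covariate. P-values were adjusted with the Benjamini-Hochberg method over the 8358 genes that passed the filter, and 0.05 was the threshold. Adjusted p-values for single genes come from this test. CPM values are the counts divided by the library total times its TMM factor (0.8759 to 1.17), and errors are standard deviations over the 3 libraries of a group. Fold changes are log2, KO less Con. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The column totals of 8875022 to 11436216 counts let a gene at 1 CPM rest on about 10 counts per library, so values under that level are imprecise.

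Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 28 lists with at least 5 tested genes, and then with a correlation estimated per list and with fry. Adjusted p-values given for lists are from camera. The 32 lists cover poly(A) polymerases and other terminal nucleotidyltransferases, cleavage and polyadenylation factors, deadenylases, the nuclear RNA exosome, histones, ribosomal proteins, oxidative phosphorylation, leukemia self-renewal, blood cell lineages, stroma, p53 targets, apoptosis, DNA replication, mitosis, ribosome biogenesis, interferon, NF-kB, immediate early, stress, glycolysis and hypoxia, cholesterol synthesis and the 4 lists named above. The lists, the groups, the tests, the alternatives and the naming rule were fixed before the data were examined, except for 5 further lists in the closing section and 1 alternative that sums Con replicates 2 and 3. The naming rule takes Papola, the 12 genes with the highest and the 12 with the lowest log2 fold change among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups (leaving out predicted genes and pseudogenes), the 4 members of each list with the smallest adjusted p past the threshold, and the 4 genes with the smallest p in each direction. It took 135 genes. Those the text names are drawn from these, and any other is said to be named after its values were seen.

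Replicates were compared before averaging by a chi-square test of each pair's counts. Con replicates 2 and 3 differed far less than other pairs (chi-square per degree of freedom 1.68) but by more than counting noise alone (p = 2.81e-293 over 8300 genes). They were kept as 2 samples because the labels list them as such. The test does not show that they came from separate animals, and the number of changed genes with them summed as 1 sample is given among the alternatives. The other pairs of a group gave 17.7 to 23.7. The biological coefficient of variation was 8.27% in Con and 14% in KO. Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, a fit that is not robust, 3 other scalings, no filter and a stricter filter (at least 10 counts in 3 libraries and a mean log2 CPM of 1), a fit without erythroid and ribosomal protein genes, a replicate block, a threshold of a 2-fold change and leaving out each library in turn. Transcript lengths for a check of length bias came from GENCODE transcripts and were found for 8205 of the tested genes (98.2%). The tests were tried on simulated data for this comparison, with 7909 genes tested and 200 changed by known amounts before filtering. The edgeR test recovered 94.9% of genes changed 2-fold and 98.98% of those changed 4-fold, with 13 false calls (6.404%). Most simulated genes were unchanged, while 82% of tested genes passed the threshold in the data, so these rates may not hold there. On 200 unshifted lists, camera gave an unadjusted p under 0.05 for 4 and fry for 7, and neither passed any after adjustment. The simulated genes were drawn independently of each other. This check therefore does not cover lists whose genes move together, and the correlation estimated in the data reached 0.674 for ribosomal proteins. The weighing of cell shares in the closing section first compared the medians of the erythroid and the basophil, mast cell and eosinophil lists (difference 3.35, permutation test, 100000 resamples, p = 0.00065). That was set aside, after the results were seen, because members of the latter list go both ways, and the directions of the members were compared instead. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.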

Results

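RNA was measured in 6 bone marrow samples of mice with acute myeloid leukemia. By their labels, 3 of them, called Con, carry a Papola gene flanked by recombination sites but intact, and the other 3, called KO, a knockout of it. Papola encodes poly(A) polymerase alpha, the canonical nuclear enzyme that adds the poly(A) tail to the 3' end of newly cleaved messenger RNA. The comparison was set up to address what loss of this enzyme does to gene expression in the leukemia. Counts for 9295 genes of the type mRNA summed to 11253932 to 11436216 per Con library and to 8875022 to 9768143 per KO library. They include 42.1% of the protein-coding genes of the mouse reference, so the sums are not the full sequencing depth. Counts were more concentrated in the libraries labelled KO. The 10 most abundant genes held 17.36% to 19.17% of counts there and 11.07% to 12.95% in the libraries labelled Con. The most abundant gene was S100a9, a subunit of the neutrophil protein calprotectin, in each KO library, and Fth1, the ferritin heavy chain, named after its values were seen, in each Con library.

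Papola itself (gene ID 18789) was not lower in the libraries labelled KO. Its counts were 3751, 3779 and 3642 in Con replicates 1, 2 and 3, and 2928, 2929 and 2440 in KO replicates 1, 2 and 3. After TMM scaling the level was 290.8 ± 6.42 counts-per-million (CPM) in Con and 339.2 ± 23.8 CPM in KO (SD, n = 3 each). The log2 fold change was 0.22 (SE 0.08), a 1.17-fold higher level in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0291). With library size as the only scaling the sign turned, with 328.8 ± 4.59 CPM in Con, 300.0 ± 25.1 CPM in KO and a log2 fold change of -0.13 (adjusted p = 0.187). Upper-quartile scaling gave 0.14 (adjusted p = 0.167), and leaving out any 1 library other than KO replicate 3 also put the adjusted p above the threshold (0.0614 to 0.0814). The counts are per gene, and counts over the deleted exons alone were not analysed here, so the level of the gene does not check the labels. Every direction given here is therefore drawn from the labels alone, as the libraries labelled KO against the libraries labelled Con.

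**Figure D1:**
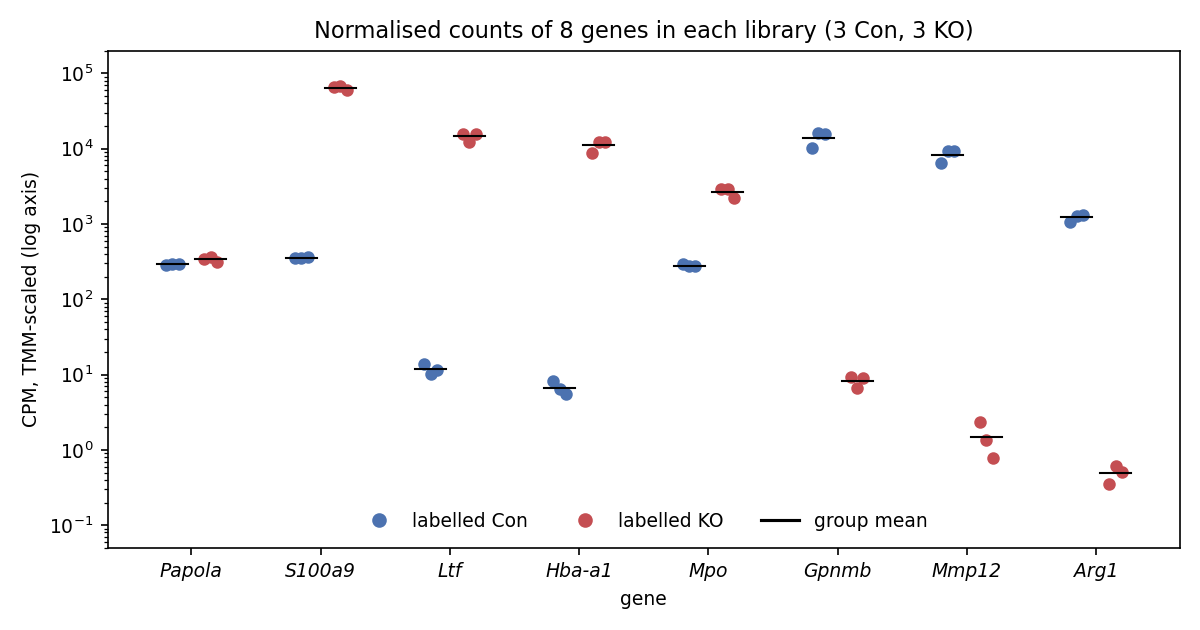
TMM-scaled CPM (log axis) of 8 genes in each library labelled Con (blue) or KO (red), with the group mean as a black line. Papola lay at 284.2 to 361.3 CPM in all 6 libraries, while S100a9, Ltf, Hba-a1 and Mpo were higher and Gpnmb, Mmp12 and Arg1 lower in each of the 3 KO libraries.

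The groups differed across most of the measured transcriptome. Of 8358 genes tested, 6854 (82%) passed an adjusted p of 0.05, 3310 of them higher and 3544 lower in the libraries labelled KO. At least 2-fold changes accounted for 1906 of the higher and 1990 of the lower genes, and changes of at least 16-fold for 344 and 263. In 84.5% of tested genes the 3 values of a group lay outside the range of the other group, where chance gives 10%. Libraries of a group correlated at 0.99 or above on the log2 CPM scale and libraries of different groups at 0.823 or below. With library size as the only scaling, the share of higher genes among those changed was 35.7% in place of 48.3% (2488 higher and 4476 lower), and the median of all log2 fold changes moved by -0.36. In each of the 135 genes chosen by the naming rule except Papola the direction was the same under every scaling, and in all 135 the 3 values of a group lay outside the range of the other group after TMM scaling. The rule requires no overlap for the genes of highest and lowest fold and takes most others by small p. Both results therefore follow largely from the choice of genes.

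**Figure D2:**
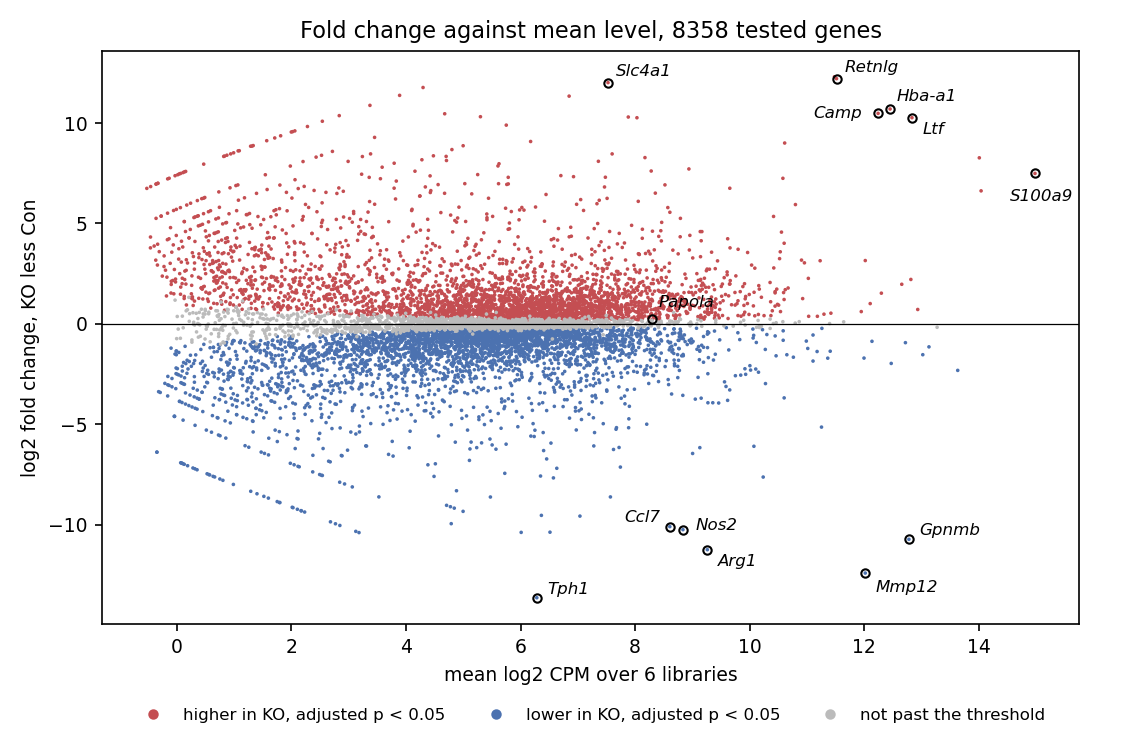
Log2 fold change, KO less Con, against the mean log2 CPM over 6 libraries for each of the 8358 tested genes; red and blue points passed an adjusted p of 0.05. S100a9, Retnlg and Hba-a1 combine a high mean level with a large positive change, Gpnmb and Mmp12 a high level with a large negative change, and Papola lies near 0 (0.22, and -0.13 with library size as the only scaling).

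Genes of maturing neutrophils were far higher in the libraries labelled KO. Of 29 late neutrophil genes tested, 27 rose and 2 fell, with a median log2 fold change of 4.36 (camera, adjusted p = 2.02e-09, and adjusted p = 0.414 with an estimated correlation). Together they took 18.1% of counts in KO and 1.25% in Con. Camp (gene ID 12796), which encodes the antimicrobial peptide cathelicidin, went from 6.76 ± 0.471 to 9685 ± 556 CPM, a log2 fold change of 10.48 (SE 0.15, adjusted p = 4.79e-10). S100a9 (20202) went from 358 ± 7.20 to 64318 ± 3791 CPM (7.49, SE 0.14), Ngp (18054), a granule protein, from 107 ± 0.602 to 32863 ± 3784 CPM (8.27, SE 0.15), and Ltf (17002), lactoferrin, from 11.8 ± 1.77 to 14584 ± 1916 CPM (10.27, SE 0.20). Retnlg, a resistin-like cytokine (12.21, SE 0.31), and the surface protein Cd177 (9.01, SE 0.18) rose as well, as did the receptor gene Trem3 (5.00, SE 0.10). Of 14 genes of primary granules and promyelocytes, the earlier stage of the lineage, 12 rose and 2 fell (median 1.64, adjusted p = 0.00502, and adjusted p = 0.592 with an estimated correlation). Mpo, myeloperoxidase, rose from 281 ± 11.8 to 2664 ± 368 CPM (3.25, SE 0.12), and Prtn3, proteinase 3, Fcnb, ficolin B, and Cebpe, a transcription factor of granulocyte maturation, rose by 4.41, 6.82 and 3.46. The receptor genes Mrgpra2a and Mrgpra2b, near-identical copies whose reads may be split between them, were at least 534-fold higher and 2980-fold higher (95% counting interval 1020 to 14500). No Mrgpra2a read was counted in any Con library, so its value is a lower bound set by a floor of 3 counts over the group.

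Erythroid genes followed the same direction. Of 24 tested, 23 rose and 1 fell, with a median log2 fold change of 3.26 (adjusted p = 2.36e-07, and adjusted p = 0.51 with an estimated correlation), and the list took 2.17% of counts in KO and 0.128% in Con. The alpha-globin genes Hba-a1 (15122) and Hba-a2 (110257) went from 6.71 ± 1.33 to 11198 ± 2092 CPM and from 1.12 ± 0.406 to 5715 ± 1375 CPM. Their log2 fold changes of 10.70 and 12.30 are uncertain as single values, since reads of these copies may be split between them. Alas2, the erythroid enzyme that starts heme synthesis, rose by 10.30 (SE 0.27) and the membrane skeleton gene Epb42 by 6.98 (SE 0.27). Slc4a1, the anion exchanger of red cells, had 3 counts over the Con group and was 4770-fold higher in KO (counting interval 1630 to 23200). Trim10, with 2 counts over the Con group, was 1550-fold higher (430 to 12800). The megakaryocyte and platelet list did not move as a whole. Of its 10 genes 4 rose (3 adjusted over the list alone) and 2 fell, with a median of 0.07 that was negative with upper-quartile scaling and with library size only (-0.01 and -0.28; camera adjusted p = 0.841). The platelet tubulin gene Tubb1 (4.71, SE 0.34) and Gp1bb (2.65, SE 0.25) rose, and Vwf, von Willebrand factor, fell by 3.04 (SE 0.18).

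More lymphoid and stromal markers rose than fell in the libraries labelled KO, but the 4 most abundant T and NK cell genes in Con and the 4 most abundant stromal ones fell. B cell genes took 0.0227% of counts in KO and 0.0101% in Con, T and NK cell genes 0.0248% and 0.0968%, and genes of stroma, endothelium and bone 0.0597% and 0.745%. Of 12 B cell genes 8 rose and 1 fell (median 5.42, adjusted p = 0.0333, and adjusted p = 0.624 with an estimated correlation). The 4 smallest p-values belonged to genes of B cell precursors. Dntt, terminal deoxynucleotidyl transferase, rose from 0.158 ± 0.140 to 54.5 ± 22.0 CPM (8.34, SE 0.55), the recombinase gene Rag1 by 7.11 and the surrogate light chain gene Vpreb1 by 6.22. Vpreb2, with no count in Con, was at least 59.2-fold higher. The call of this list was lost without KO replicate 2 (adjusted p = 0.053), without KO replicate 3 (0.0643) and under a stricter count filter (0.0528). Of 19 T and NK cell genes 14 rose and 5 fell (median 3.14, adjusted p = 0.0201, and adjusted p = 0.592 with an estimated correlation), and the stricter filter ended that call (0.109). Cd4 rose by 7.37 (SE 0.34) and the NK receptor gene Klrb1c by 6.03 (SE 0.32), while the cytotoxic protease gene Gzmb fell from 303 ± 96.7 to 7.10 ± 0.768 CPM (-5.41, SE 0.26) and the costimulatory receptor gene Cd28 from 113 ± 13.9 to 5.52 ± 2.50 CPM (-4.37, SE 0.25). Of 13 genes of stroma, endothelium and bone 9 rose and 4 fell (median 4.05, adjusted p = 0.107). With library size only that list passed (adjusted p = 0.0177). The sinusoidal endothelial receptor gene Stab2 rose by 8.68 (SE 0.31), Cdh5, VE-cadherin, by 4.57 and Dcn, decorin, by 4.33, and the collagenase gene Mmp13 fell from 1318 ± 193 to 85.7 ± 19.1 CPM (-3.94, SE 0.18). Sele, the endothelial adhesion molecule E-selectin, was at least 201-fold higher.

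Monocyte and macrophage genes split. Of 27 tested, 18 rose and 9 fell, with a median log2 fold change of 2.16 (adjusted p = 0.0061, and adjusted p = 0.624 with an estimated correlation). Apoe rose from 7.11 ± 0.996 to 650 ± 114 CPM (6.51, SE 0.18), Vcam1 by 4.71 (SE 0.16), the chemokine receptor gene Ccr2 by 3.66 (SE 0.10) and Ly6c2 by 3.14 (SE 0.12). The 9 that fell, named after their values were seen, were Cd68 (-2.89), Adgre1, which encodes the F4/80 antigen (-2.67), Marco, Ms4a7, Cd14, Cd74 and the class II genes H2-Eb1, H2-Ab1 and H2-Aa (-0.59). Of 17 basophil, mast cell and eosinophil genes 8 rose and 8 fell (camera adjusted p = 0.949, with a test direction of up against a median of -0.08, or -0.44 with library size only, and a mean of -0.18). The 8 that fell, listed after their values were seen, were mostly basophil or mast cell genes (Cpa3, Mcpt8, Ms4a2, Prss34, Cd200r3, Cma1, Il4 and Gata2). The 8 that rose were mostly eosinophil genes (Ear1, Ear2, Ear6, Ccr3, Prg2 and Prg3, besides Hdc and Il6ra). The median near 0 thus pools genes that moved apart. The eosinophil ribonuclease genes Ear1 and Ear2, close copies whose reads may be shared, rose by 4.17 and 3.87, Ccr3 rose by 7.43 (SE 0.30), and the mast cell protease gene Cpa3 fell from 419 ± 55.7 to 42.9 ± 9.76 CPM (-3.29, SE 0.18).

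Several of the genes with the steepest falls in the libraries labelled KO were abundant in those labelled Con. Mmp12 (17381), macrophage metalloelastase, went from 8292 ± 1580 to 1.49 ± 0.791 CPM (log2 fold change -12.41, SE 0.31, adjusted p = 4.64e-09). Gpnmb (93695), a lysosomal glycoprotein of macrophages, went from 14058 ± 3451 to 8.26 ± 1.5 CPM (-10.73, SE 0.29). Both enzymes that compete for arginine fell, Arg1 (11846), arginase, from 1223 ± 128 to 0.494 ± 0.134 CPM (-11.25, SE 0.19, adjusted p = 1.27e-09) and Nos2 (18126), inducible nitric oxide synthase, from 909 ± 82.1 to 0.722 ± 0.491 CPM (-10.25, SE 0.23). The chemokine gene Ccl7 fell by 10.10 (SE 0.32). Tph1, which encodes tryptophan hydroxylase, and Ido2, which encodes an indoleamine dioxygenase, had no count in KO and were at least 1250-fold and 131-fold lower. Ccn3 was 1460-fold lower (counting interval 501 to 7110) and Ahnak2 1530-fold lower (423 to 12600).

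Inflammatory genes fell in the same libraries, in which the alpha-globin genes rose to 1.14% or more of counts from at most 0.00109%. Of 28 NF-kB and inflammatory response genes 26 fell and 1 rose, with a median of -1.83 (adjusted p = 3.39e-06, and adjusted p = 0.51 with an estimated correlation). Ccl2, a monocyte chemokine, went from 2397 ± 468 to 12.1 ± 2.24 CPM (-7.63, SE 0.22), Il1a, interleukin-1 alpha, from 1012 ± 89.7 to 11.5 ± 1.94 CPM (-6.46, SE 0.15) and Cxcl3 from 1101 ± 17.8 to 15.4 ± 3.35 CPM (-6.17, SE 0.15). Traf1 fell by 4.32 and Tnip3, an inhibitor of NF-kB signalling outside that list, by 7.44 (SE 0.16). Immediate early genes went the other way, with 22 of 31 higher and 6 lower (median 2.04, adjusted p = 0.00237, and adjusted p = 0.592 with an estimated correlation). Zfp36, a protein that promotes decay of AU-rich messenger RNA, rose from 122 ± 7.02 to 2890 ± 554 CPM (4.57, SE 0.16), the phosphatase gene Dusp1 by 3.78 (SE 0.15), Gadd45a by 3.62 (SE 0.15) and Jund by 2.00 (SE 0.09). Interferon-stimulated genes showed no common direction, with 10 of 27 higher, 9 lower and a median of 0.02 (adjusted p = 0.91) that was -0.33 with library size only and -0.07 with upper-quartile scaling. Samhd1 (1.91, SE 0.08) and Sp100 (1.51, SE 0.07) rose, and Usp18 fell by 2.98 (SE 0.16).

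Genes of cholesterol synthesis, of glycolysis and hypoxia, and of the integrated stress and unfolded protein response were mostly lower in the libraries labelled KO. Late neutrophil genes took 18.1% of counts in these libraries. Genes of oxidative phosphorylation, given below, were mostly higher after TMM scaling. All 24 cholesterol synthesis genes tested fell, with a median of -2.23 (adjusted p = 2.36e-07, and adjusted p = 0.414 with an estimated correlation). Sqle, squalene epoxidase, went from 199 ± 8.88 to 11.45 ± 1.39 CPM (-4.12, SE 0.11), Lss, lanosterol synthase, from 138 ± 8.21 to 6.91 ± 1.72 CPM (-4.31, SE 0.15) and Hmgcs1 from 305 ± 7.82 to 54.0 ± 2.92 CPM (-2.50, SE 0.08). Of 24 genes of glycolysis and hypoxia 21 fell and 2 rose (median -1.74, adjusted p = 1.18e-05, and adjusted p = 0.414 with an estimated correlation). Ero1a fell from 2881 ± 159 to 224 ± 30.8 CPM (-3.69, SE 0.12), and the hypoxia-responsive genes Egln3 and Bnip3 fell by 3.60 and 3.14. The glycolytic aldolase gene Aldoc, outside that list, fell by 5.61 (SE 0.11). Of 32 genes of the integrated stress and unfolded protein response 27 fell and 3 rose (median -1.20, adjusted p = 7.14e-05, and adjusted p = 0.229 with an estimated correlation). Pdia4, a disulfide isomerase of the endoplasmic reticulum, fell from 596 ± 52.7 to 81.2 ± 15.2 CPM (-2.87, SE 0.14), the lipoprotein receptor gene Vldlr by 4.05 (SE 0.18) and the transcription factor gene Atf5 by 1.92 (SE 0.10).

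Cell cycle genes rose and genes of ribosome biogenesis fell in the libraries labelled KO, in which erythroid genes took 2.17% of counts. Of 36 mitosis genes 30 rose and 1 fell (median 0.67, adjusted p = 5.2e-05, and adjusted p = 0.592 with an estimated correlation), and of 23 DNA replication genes 18 rose and 3 fell (median 0.60, adjusted p = 0.00237, and adjusted p = 0.592 with an estimated correlation). With library size only, these counts were 19 and 3 (median 0.31), and 13 and 3 (median 0.24). Birc5, survivin, rose from 76.7 ± 2.46 to 260 ± 14.0 CPM (1.76, SE 0.08), the cyclin gene Ccna2 by 1.42 (SE 0.09), Slbp, the histone stem-loop binding protein, by 1.44 (SE 0.09) and the helicase gene Mcm5 by 0.96 (SE 0.09). Of 43 MYC targets in ribosome biogenesis 32 fell and 2 rose (median -0.37, adjusted p = 0.00121, and adjusted p = 0.592 with an estimated correlation), but 39 fell and 0 rose with library size only (median -0.73). Utp4 and Nop14 were each at -1.35 (SE 0.10). Myc itself fell from 179 ± 8.02 to 62.1 ± 3.29 CPM (-1.53, SE 0.08). Of the 23 leukemia self-renewal genes 13 fell and 7 rose (median -0.44, or -0.79 with library size only, adjusted p = 0.521). Gata2 fell by 2.79 (SE 0.16) and Dot1l, a histone methyltransferase, by 1.41 (SE 0.09), and Lmo2 rose by 1.07 (SE 0.07). Of 24 p53 target genes 17 fell and 4 rose (median -0.95, adjusted p = 0.0187, and adjusted p = 0.592 with an estimated correlation). The stress cytokine gene Gdf15 fell from 95.4 ± 12.7 to 2.60 ± 0.760 CPM (-5.20, SE 0.19), Zmat3 by 2.69 and the proapoptotic gene Bax by 1.49, and Btg2, which is also an immediate early gene and a deadenylase cofactor, rose by 3.28 (SE 0.20). Among 26 apoptosis regulators 12 fell and 9 rose (median -0.17, adjusted p = 0.718), and with library size only 16 fell and 6 rose (median -0.52). Bcl2a1a, Bcl2a1b and Bcl2a1d, copies of a survival gene whose reads may be shared, fell by 3.12, 3.15 and 3.73.

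Genes of messenger RNA 3' end formation and decay moved in both directions between groups that also differed in the share of late neutrophil genes (18.1% against 1.25%). Of all genes tested 82% passed the threshold, a share that none of these lists reached after TMM scaling. The counts of passing members therefore do not mark these lists as more changed than other genes. Of 7 poly(A) polymerases and other terminal nucleotidyltransferases tested, 2 rose and 3 fell (median -0.09, or -0.44 with library size only, adjusted p = 0.943). Papola, whose sign depends on the scaling, is 1 of the 2 that rose, and 1 rose and 4 fell with library size only. Tut7, a uridylyltransferase, rose from 130 ± 3.27 to 282 ± 44.6 CPM (1.11, SE 0.11), Tut1 fell from 56.6 ± 5.97 to 17.3 ± 2.54 CPM (-1.71, SE 0.13), and Tent4b, a noncanonical poly(A) polymerase, fell by 0.30 (SE 0.09), a call lost without Con replicate 3 (adjusted p = 0.0596). Of 14 cleavage and polyadenylation factors 5 rose and 5 fell (4 fell adjusted over the list alone), with a median of -0.06, a mean of 0.03 and a camera direction of up (adjusted p = 0.949). With library size only, 1 rose and 8 fell (median -0.41). The scaffold gene Sympk fell by 0.74 (SE 0.08) and Cpsf1, the largest subunit of the cleavage complex, by 0.60 (SE 0.09). Ppp1ca, a phosphatase subunit, rose by 1.10 (SE 0.08) and Ssu72 by 0.43 (SE 0.08), the latter not past the threshold with library size only (0.07, adjusted p = 0.473). Of 18 deadenylase genes, which include cofactors, 10 rose and 4 fell (median 0.28, adjusted p = 0.211), but 5 rose and 7 fell with library size only (median -0.07). Their largest changes were in the cofactors Btg2 and Tob1 (2.33, SE 0.18), with smaller rises of Btg1 (0.92, SE 0.10) and of the deadenylase gene Pan2 (0.82, SE 0.09). Of 13 genes of the nuclear RNA exosome and its adaptors 2 rose and 4 fell (adjusted p = 0.949), with a median of 0.01, a test direction of down, and medians of -0.35 with library size only and -0.08 with upper-quartile scaling. The counts with library size only were 2 higher and 9 lower. Exosc5 rose by 1.05 (SE 0.10) and the catalytic subunit gene Dis3 fell by 0.68 (SE 0.11).

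Genes of replication-dependent histones, ribosomal proteins and oxidative phosphorylation were mostly higher after TMM scaling in the libraries labelled KO, in which late neutrophil genes took 18.1% of counts against 1.25% and erythroid genes 2.17% against 0.128%. All 25 replication-dependent histone genes tested rose, with a median of 4.28 (adjusted p = 2.36e-07, and adjusted p = 0.414 with an estimated correlation). Another 14 in the table had too few counts to pass the filter, and with no filter 38 of the 39 rose and 0 fell (median 3.92). These messages normally end in a stem-loop in place of a poly(A) tail, and their counts were low. The libraries were made with an mRNA kit. Whether it captured messages without a tail was not examined, so the rise in counts need not be one of total histone RNA. H1f4 went from 0.386 ± 0.273 to 18.1 ± 2.23 CPM (5.50, SE 0.34) and H1f5 from 0.238 ± 0.214 to 11.8 ± 3.22 CPM (5.58, SE 0.44), and the whole list took 0.0311% of counts in KO and 0.00806% in Con. Histone genes are near-identical copies, and reads may be shared among them. Of 35 ribosomal protein genes 22 rose and 2 fell over all genes tested, and 22 rose and none fell adjusted over the list alone (median 0.41, adjusted p = 0.0054, and adjusted p = 0.688 with an estimated correlation). With library size only, 9 rose and 8 fell, the median was 0.06 and the call was lost (adjusted p = 0.113). Fau rose from 546 ± 40.7 to 1406 ± 97.4 CPM (1.36, SE 0.10) and Rps9 from 1147 ± 107 to 2742 ± 67.0 CPM (1.26, SE 0.10). Of 36 nuclear-encoded genes of oxidative phosphorylation 23 rose and 5 fell (4 fell adjusted over the list alone), with a median of 0.50 (adjusted p = 0.00323, and adjusted p = 0.592 with an estimated correlation). With library size only, 17 rose and 10 fell (median 0.15). The complex I genes Ndufb7 and Ndufb11 rose by 1.66 (SE 0.10) and 1.55 (SE 0.09). Fold changes also varied with transcript length over all genes. With genes split by length into 5 groups of 1641, the median log2 fold change was 0.21 in the group of shortest transcripts and -0.32 in that of the longest.

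**Figure D3:**
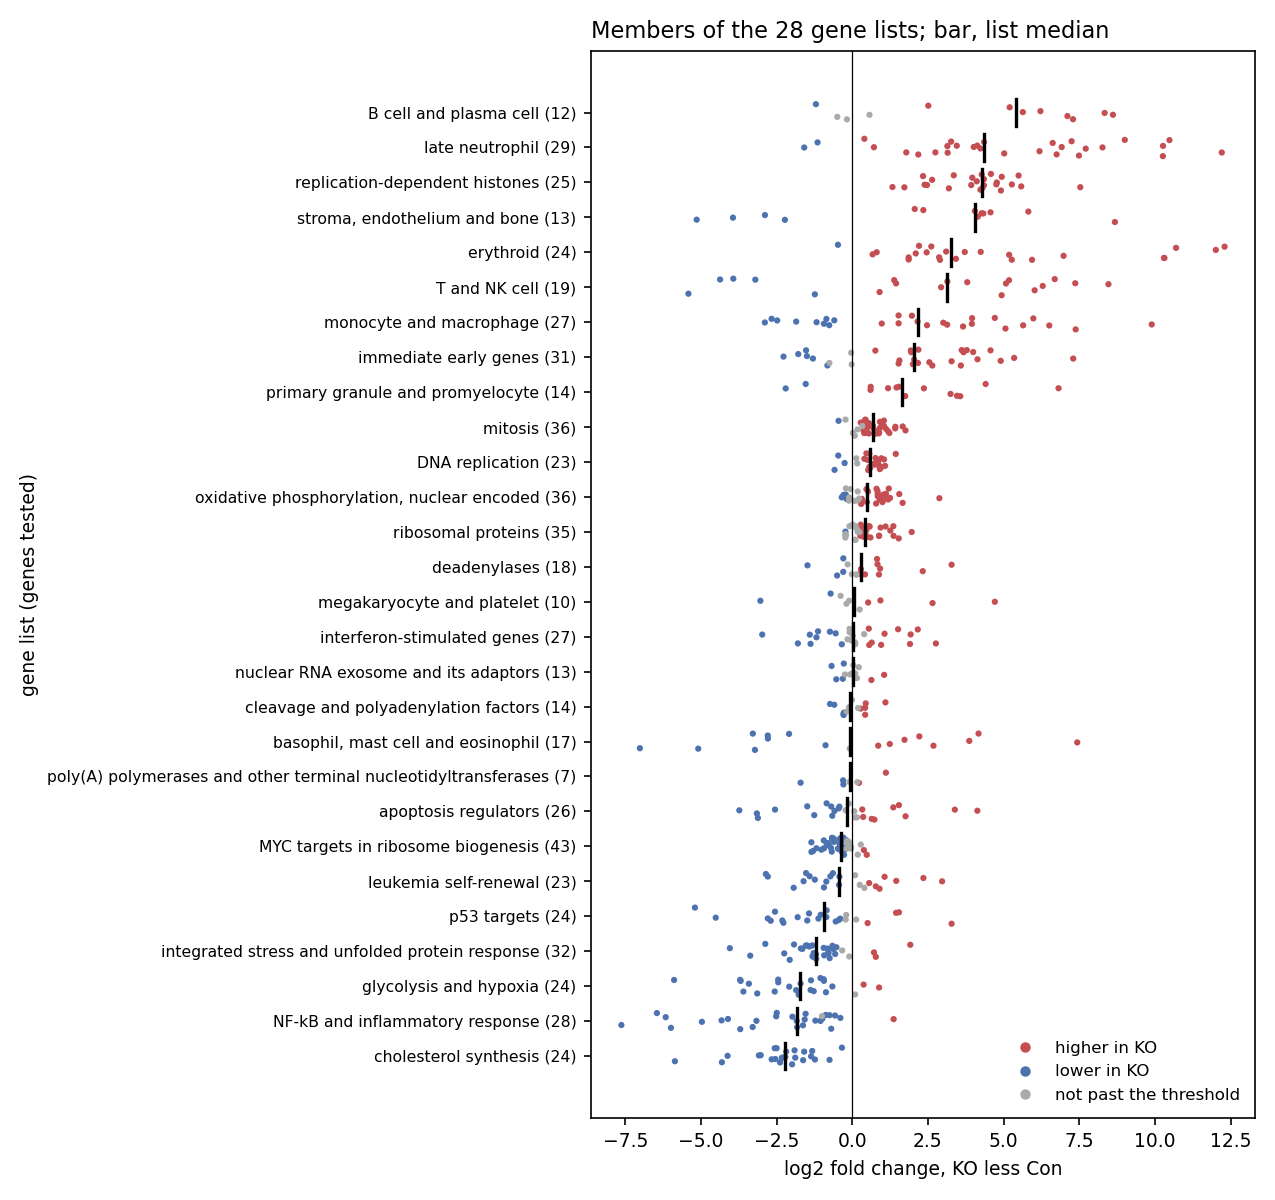
Log2 fold change, KO less Con, of each tested member of 28 gene lists (points, with the number of members in brackets) and the list median (black bar). Medians run from -2.23 for cholesterol synthesis to 5.42 for B cell and plasma cell genes, and those of the deadenylase, megakaryocyte, interferon and exosome lists, all near 0, turn negative with library size as the only scaling.

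Of the 28 lists with tested genes, 18 passed in camera with its preset correlation, 12 of them up and 6 down. None passed with a correlation estimated from these 6 libraries, where the lowest adjusted p was 0.229 and 2 lists had an unadjusted p under 0.05, while the rotation test fry, which asks whether a list's genes move one way on balance, passed 23. In 24 of the 28 lists the counts of higher and lower genes adjusted over the list alone equalled those over all genes tested, and the other 4 are given with both counts. In camera with its preset correlation, other splits of the 6 libraries also passed 12 to 16 lists. A list past that test therefore does not by itself set the real grouping apart from those splits.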

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

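The count of changed genes was between 6438 (stricter filter) and 7215 (no filter) over all alternatives that keep the threshold, against 6854, and no gene called in both changed direction in any of them. Adding a 2-fold change to the threshold left 3896 genes, 1906 higher and 1990 lower, which follows from the threshold. Leaving out 1 library gave 6485 to 6855 genes. Con replicates 2 and 3 summed as 1 sample, an alternative chosen after seeing the data, gave 6557 (3201 higher, 3356 lower). DESeq2 called 6706 and limma-voom 6854. Same-numbered libraries of the groups did not deviate together (correlations of -0.002, 0.028 and -0.004). That shows no pairing by number but cannot exclude one, and the labels do not state any. With the replicate block 6766 genes changed (3270 higher, 3496 lower), 18 lists passed and Papola stood at 0.22 (adjusted p = 0.0463), and no call of a named gene or a list changed. The Papola value was least stable. It was 0.1362 with upper-quartile factors (adjusted p = 0.167), -0.1324 with library size only (0.187), 0.2355 with Con replicates 2 and 3 as 1 sample (0.0868), and 0.1715 to 0.2733 on leaving out 1 library, with adjusted p from 0.00857 without KO replicate 3 to 0.0814. Over all alternatives its adjusted p ran from 0.00374 to 0.187. Library size only lowers every KO level against Con relative to TMM (median shift of log2 fold change -0.355), by more than the 0.22 of Papola. The sign of Papola thus depends on the scaling, and which scaling is right was not tested. The cause of the other changes was not tested either. Of the other 134 genes of the naming rule 132 kept direction and call in every alternative that gave a value, and 2 were weaker, Ssu72 with library size only and Tent4b without Con replicate 3. Since the rule picks genes by small p or large change, it favours such stability. Leaving out erythroid and ribosomal protein genes gave no value for 10 of them, and the stricter filter none for 1. Of gene lists, 18 passed in each scaling and 16 to 18 in the filters and on leaving out 1 library, but 0 with an estimated correlation (camera, 2 at an unadjusted p under 0.05, the lowest 0.00818) and 23 with fry. An estimate from 6 libraries is imprecise, and its part in that loss was not tested. Depth limits histone and lymphoid genes, of which 5 of 25 histone, 4 of 12 B cell and 9 of 19 T and NK cell genes had a mean of 1 CPM or more in Con.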

Other observations

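Some gene groups beyond the fixed lists, chosen after their values were seen and so no independent evidence of their direction, also differed. Of 33 genes of lysosomal proteins 29 fell and 3 rose in the libraries labelled KO, with a median log2 fold change of -1.59 (camera, adjusted p = 9.76e-06, and adjusted p = 0.555 with an estimated correlation), and the list went from 6.12% to 1.18% of counts. In the same libraries late neutrophil genes went from 1.25% to 18.1% of counts, and the macrophage gene Adgre1 fell by 2.67. The cathepsin gene Ctsd fell from 9045 ± 1542 to 2307 ± 261 CPM (-1.97, SE 0.15) and Psap, which encodes the saposins, from 12371 ± 1892 to 4263 ± 1034 CPM (-1.54, SE 0.19). Of 22 chemokine ligand genes 15 fell and 5 rose (median -3.43, adjusted p = 0.00884, and adjusted p = 0.363 with an estimated correlation). Ccl22 and Ccl24 fell by 9.57 (SE 0.37) and 9.54 (SE 0.38), Ccl9 went from 1658 ± 166 to 290 ± 46.5 CPM, and Cxcl9 rose by 4.81 (SE 0.33).

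Genes of iron handling split, with 5 of 11 higher and 6 lower (median -0.47, mean 0.97, adjusted p = 0.937). The ferritin genes Fth1 and Ftl1 fell from 21146 ± 2252 to 4242 ± 883 CPM and from 12346 ± 1586 to 5578 ± 768 CPM. The iron exporter gene Slc40a1 rose from 17.9 ± 2.37 to 407 ± 19.4 CPM, and Cd163, the receptor for haptoglobin-bound hemoglobin, from 0.103 ± 0.0417 to 111 ± 33.2 CPM. Of 11 genes of plasmacytoid dendritic cells 7 rose and 3 fell (median 2.35, adjusted p = 0.116), with Siglech up by 9.08 (SE 0.30). Of 11 class I and class II histocompatibility genes 3 rose and 7 fell (median -0.76, adjusted p = 0.572), with H2-Q10 up by 5.35 (SE 0.22) and H2-Aa at -0.59 (SE 0.24). Values of single histocompatibility genes are uncertain where near-identical copies share reads.

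Of the tests below, those of lineage genes and of Papola were chosen only after the results were seen, and those of transcript length and of the sample splits before. Erythroid and late neutrophil genes were far higher in the libraries labelled KO. A single mislabelled library or an exchange of some but not all libraries between the groups is argued against by correlations of at most 0.823 between groups and at least 0.99 within them. A lower share of 1 main cell type that lacks basophil and mast cell genes would raise every other type alike. Against that, 8 of 17 basophil, mast cell and eosinophil genes fell, 5 of them with 100 CPM or more in Con, and 8 rose. Those that fell were mostly basophil or mast cell genes, and those that rose mostly eosinophil genes. Of 24 erythroid genes 23 rose (Fisher's exact test across genes, which are not independent replicates, p = 0.00117). That test was set once these counts were known, so its p-value is no independent evidence. A lower share of a type that carries the genes that fell is not argued against. A difference in cell source or in the share of leukemic cells, apart from or through the genotype, is a candidate explanation. Leukemic cells could carry those basophil and mast cell genes themselves. The alpha-globin genes take at most 0.00109% of counts in every Con library and at least 1.14% in every KO library. In lists of unlike lineages more genes rose than fell, with 23 erythroid genes higher and 1 lower, and 8 and 1 for B cells. The counts were 14 and 5 for T and NK cells, and 9 and 4 for stroma. But the T and NK cell list went from 0.0968% of counts in Con to 0.0248% in KO. The stroma list went from 0.745% to 0.0597% and did not pass in camera (adjusted p = 0.107). These values go with unlike cell content. That content and the genotype label coincide in every library. The reason for it, and an effect of Papola inside the cells, therefore cannot be told apart. No sort is named that would remove red cells or neutrophils, none of the 24 erythroid or 29 late neutrophil genes is on another fixed list, and 20 and 28 of them have a mean of 1 CPM or more in Con.

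Papola was not lower in the libraries labelled KO. The lowest log2 fold change over all alternatives was -0.1324 (SE 0.09), with library size only, so none of them showed a large loss. The scalings tried shift log2 fold changes by only 0.054 to -0.355 against TMM, so none could have turned 0.22 into one. All of them set Papola against the counts of other genes. The check therefore cannot exclude that scaling hides a loss of Papola per cell. Reads from exons outside the deleted part may keep the count of the gene up, and so might cells with an intact gene or exchanged group labels. The value of 0.22 (SE 0.08) comes from counts per gene, so these cannot be told apart without counts per exon, which were not analysed here.

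Ribosomal protein genes, genes of oxidative phosphorylation and histone genes were higher in the libraries labelled KO, and log2 fold change fell with transcript length over 8205 genes (Spearman's rho -0.121 across genes, which are not independent replicates). Less the length trend of all other genes, the ribosomal protein median went from 0.40 to -0.07 (bootstrap SE 0.09), so the list did not stand apart from that trend. The trend was fitted on genes of the same comparison. It may itself follow cell content, so it is not shown to be a separate source. With library size only, the ribosomal protein median was already 0.06. For oxidative phosphorylation the median less the trend went from 0.48 to 0.09 (SE 0.13), too close to its bound of 0.242 to decide. For histones it went from 4.28 to 3.59 (SE 0.34), which argues against length as the whole cause. An effect of the Papola knockout itself, the difference the design names, stays open and was not tested apart from the group difference for any of the 3 lists. Whether the mRNA kit captured histone messages only by a tail was not examined either.

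The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 6854 genes passed, 3310 higher and 3544 lower, where the highest other count was 0 in each case. For gene lists, in camera with its preset correlation, 1 of the 10 splits gave as many as the real 18, and the others gave 12 to 16. The number of lists past that test therefore sets the real grouping little apart, and its adjusted p-values alone do not show a group difference. The other splits mix the groups unevenly, so part of the group difference may remain in them.

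Con replicates 2 and 3 lay closer together than any other pair of libraries in a group, with a chi-square per degree of freedom of 1.68 against 17.7 to 23.7. Whether they came from the same animal is not stated in the labels.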
